A study of Mus musculus with 6 samples.

How the data were processed

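Accessible chromatin was profiled by ATAC-seq, in which the Tn5 transposase cuts open DNA and inserts sequencing adapters, in immature B cells (B220+CD93+) of the spleen. The mice were of the Tcrd-GDL strain, a reporter line whose γδ T cells carry the diphtheria toxin receptor and are removed by the toxin. Per the labels, 3 libraries came from untreated mice and 3 from mice given diphtheria toxin (DTx), as 2 intraperitoneal injections of 15 ng per gram of body weight 48 h apart, with the cells taken on day 8 after the first injection. Nuclei were isolated with a commercial kit and tagmented with Illumina's TDE1 enzyme, per the labels' protocols. The labels number the libraries within each group but do not state that they came from separate mice, so p-values measure the spread between these samples, which may be technical.

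Reads were trimmed with Trim Galore 0.4.3, aligned to mm10 with Bowtie2 2.3.2 and passed to MACS2 2.1.1, per the submitters' processing notes. Whether the read ends were shifted for the Tn5 cut, whether duplicates were removed and how many reads each library held are not given in the sources used here. The deposited data are 1 peak list per library, called on each library separately. Each list gives the position of a peak, its length, its pileup (the read coverage signal, per the file headers), its fold enrichment over the background as a ratio, also per the file headers, and the −log10 of its p-value and q-value. The headers of those last 2 columns are damaged in the deposited lists, and the columns were identified from their order and values. These numbers are the authors' own for each peak and were used only to describe, rank or filter peaks within a list. The lists were of 2 kinds. Untreated replicate 3 and DTx replicate 1 had a summit column, whole-number pileups and a lowest −log10 q of 1.33 and 1.30, which is the layout of MACS2's narrow mode. The other 4 deposited lists had no summit, fractional pileups and a lowest −log10 q between 1.00 and 1.02, which is the layout of its broad mode. Each group thus held 2 broad-mode lists and 1 narrow-mode list, and values within each mode are given beside the pooled ones for the measures per library that are described, the group-only regions, the similarity (broad mode only), the summed list members and some of the lists. With no read totals the depth is unknown, so no interval that needs it is given, and the length of a list stands as the only sign of how much was called.

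Peaks on the 19 autosomes, X and Y were kept and the 2 mitochondrial peaks of each list were left out. No peaks overlapped within a list. Regions are the merged union of the 6 lists, and a library has a region where at least 1 bp of a peak lies in it. Since a longer list alone gives more regions, equal-length lists were made from the 36760 peaks of highest −log10 q in each library, which is the length of the shortest list. A group-only region was called in 3 of 3 libraries of one group and 0 of 3 of the other. A strict group-only region was in the equal-length lists of 3 of 3 libraries of one group and under no deposited peak, of any strength, in the other 3 libraries. Similarity was the Jaccard index, the bases covered in both libraries over those covered in either. Coordinates are 1-based on mm10. The gene table used is of the GRCm38.p6 assembly, the same build, with 21887 protein-coding genes on these chromosomes. It has no strand and no exons, so a peak within 1 kb of either end of a gene, called a gene end here, took the place of a promoter, and exons and introns were not told apart. All 341 symbols of the gene lists were in it.

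Values per library were compared with an exact two-sided permutation test over the 20 relabellings, whose smallest p is 0.1, so that this test cannot reach 0.05 with 3 libraries against 3. For each protein-coding gene, peaks of the equal-length lists with their midpoint in the gene or within 50 kb of it were counted. Genes with a mean of at least 3 peaks were fitted with limma 3.58.1 in R 4.3.3 (trend and robust) on log2(peaks + 0.5), with Benjamini-Hochberg adjustment at 0.05. A fold on that scale understates the difference of genes with few peaks, and neighbouring genes share peaks. The 14 gene lists and 7 lists of markers of other cell types were compared by the number of members with a peak at a gene end, by camera on the neighbourhood fit (correlation of 0.01, and estimated), and by Fisher's exact test, one-sided for excess, among the genes nearest to group-only regions within 100 kb, against genes nearest to any region that could have passed. Other steps were run in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The comparisons, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes up to 12 strict regions per direction by the highest value of the lowest within-list percentile of −log10 q, each with the nearest gene within 100 kb. It also takes up to 5 genes per direction from the neighbourhood fit, up to 4 members of each list with a gene-end peak in 3 of 3 against 0 of 3 libraries or otherwise the member with the largest difference, and 12 identity genes. Tests of motifs need the genome sequence, which was not used here.

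The code was tested on simulated data. In lists of the real lengths over the 70174 regions, all 400 planted group-only regions were recovered under each criterion. They were planted at the top of each list of one group and kept out of the other's, which checks the code but not its power. With nothing planted, lists of deposited length gave 257 DTx-only and 2 untreated-only regions and equal-length lists 145 and 145. The strict criterion gave 1 and 0. The simulated libraries differed by list length and independent noise only, whereas another split of the real libraries gave 641 strict regions. The simulated 1 and 0 are therefore no measure of chance for the real strict counts. For the neighbourhood fit on 12566 genes, each gene's values were put in random order and 200 genes were changed. At a 2-fold change limma recovered 38% of them, and with nothing changed it called 74 genes, 71 of which had no spread within groups. A floor on the residual variance, at that of rounding to whole peaks, was chosen after seeing the data. With it limma recovered 77.5% at 2-fold beside 4 unchanged genes, and called 0 genes with nothing changed. At a 1.5-fold change it recovered 0.5% with the floor and 14% without, so the floored fit has little power for small differences. The alternatives were a −log10 q of at least 5, each replicate left out, the replicate number as a block, 500 bp windows around summits or midpoints in place of peaks, ranking by fold enrichment, autosomes only, deposited against equal-length lists, another pseudocount, filter and flank for the fit, and, added after seeing the data, each calling mode alone, a 2 kb distance to a gene end, width and covered length in equal-length lists, the tests of lists near deposited and equal-length group-only regions, the variance floor and an exact binomial test of summed peaks.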

Results

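The libraries asked how open chromatin of splenic immature B cells compares between untreated mice and mice on day 8 after the first toxin injection, given to deplete γδ T cells. The design does not separate depletion from other effects of the toxin, and these lists do not show how complete the depletion was. The untreated libraries held 36760, 42504 and 56503 peaks and the DTx libraries 44661, 56266 and 60811. The union of the 6 lists made 70174 regions, of which 30954 (44.1%) were called in all 6 libraries and 12785 (18.2%) in 1 library only.

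Peaks at B-lineage genes were present in both groups. Cd79a, which encodes a signalling chain of the B cell receptor, the transcription factor genes Pax5 and Ebf1, and Cd93, the marker used for the sort, each had a gene-end peak in 6 of 6 libraries. So did Fcer2a (CD23) and Cr2 (CD21), receptors of more mature B cells. The Cr2 peak lay between the 93.9th and the 97.6th percentile of −log10 q in its lists. Rag1, which encodes part of the V(D)J recombinase, had one in 0 of 3 untreated and 1 of 3 DTx libraries. Cd3e and Trdc of T cells, Lyz2 of myeloid cells and Gata1 of erythroid cells had none in any library. Other markers of the same lists had one in 6 of 6 libraries, named after their values were seen, with Cd3d at the 87.4th percentile or above, Lat at the 72.2nd, Klf1 at the 70.2nd and Cd68 at the 39.1st. Of 18 B lineage identity genes, 16 had a gene-end peak in all 6 libraries, and each of the 18 was called in the same number of untreated and DTx libraries.

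In 6 of the 7 lists of markers of other cell types, between 23.3% and 39.8% of members were called per library on average, and the group means of all 7 lay within 1.33 members of each other. Means of members with a gene-end peak were 7.67 ± 1.53 untreated against 7.67 ± 3.21 DTx of 20 T cell genes, 2.00 ± 0 against 2.67 ± 0.58 of 10 γδ T cell genes, and 4.33 ± 0.58 against 3.00 ± 1.00 of 12 natural killer and innate lymphoid genes (SD, n = 3 each; exact permutation p = 1, 0.4 and 0.3). In the broad mode DTx had 2.5 more T cell genes and in the narrow mode 5 fewer. They were 7.0 ± 1.73 against 7.33 ± 0.58 of 18 myeloid genes, 5.67 ± 0.58 against 6.0 ± 0 of 15 erythroid and megakaryocyte genes, and 3.67 ± 1.53 in both groups of 13 stromal and endothelial genes (SD, n = 3; exact permutation p = 1 for each). The 12 dendritic cell genes had 8.67 ± 0.58 in both groups (SD, n = 3), a share of 72.2%, above the 65.6% of the immature and transitional B list. Of these 12, 8 had one in all 6 libraries. They included Tcf4 and Irf8, which B cells also use. They also included Xcr1, at the 87.5th percentile or above, Zbtb46, Flt3, Clec9a and Siglech, named after their values were seen. Itgax, Ccr9 and Cd209a had none in any library. Whether dendritic cells were among the sorted cells was not tested. Across the 7 lists the members with the largest difference were Sox13 (0 of 3 untreated, 2 of 3 DTx), Il2rb (2 of 3, 0 of 3) and Csf1r (3 of 3, 1 of 3).

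Of the 14 lists of B cell and response genes, 1 stood at the smallest p of the exact test in the deposited lists. In equal-length lists germinal centre and plasma cell genes stood there as well, in the other direction. They had 13.0 ± 0 untreated and 11.7 ± 0.58 DTx (SD, n = 3, exact permutation p = 0.1, Benjamini-Hochberg adjusted 0.933 over 21 lists). Of all protein-coding genes, 51.1%, 51.1% and 51.6% had a gene-end peak in the untreated equal-length lists 1, 2 and 3. The DTx shares were 49.3%, 50.1% and 49.8%, the same direction, so the fall was not shown to be particular to that list. Antigen presentation and costimulation had 15.0 ± 0 of 18 members with a gene-end peak in the untreated and 16.0 ± 0 in the DTx libraries (SD, n = 3; exact permutation p = 0.1, Benjamini-Hochberg adjusted 1 over 21 lists). The difference was Cd80, the costimulatory ligand of CD28 and CTLA-4, called in 3 of 3 DTx and 0 of 3 untreated libraries. It was 1 member in the broad-mode and in the narrow-mode libraries alike. The peak lay on chromosome 16 from 38457247 to 38457482 and reached over the lower-coordinate end of the gene (38457430 to 38495958). It was of middling strength, at the 21.7th, 47.4th and 49.6th percentile of −log10 q in DTx replicates 1, 2 and 3. The MHC class II regulator Ciita and the PD-L2 gene Pdcd1lg2 had no gene-end peak in any library, and the other 15 members had one in all 6.

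The other 13 lists differed by less than 1 member between the means of the deposited lists. In equal-length lists, DTx minus untreated, immature and transitional B genes differed by -1.33 and follicular and marginal zone genes by -1. The exact permutation p was 0.4 for each, and the share of all protein-coding genes fell as well. All 22 cell cycle genes were called in all 6 libraries, as were 15 of 16 AP-1 and immediate early genes and 13 of 17 BAFF and survival genes, with no member of these lists called in more libraries of one group. Means were 22.0 ± 2.00 untreated against 22.7 ± 1.53 DTx of 26 interferon response genes, where Ifi44 was called in 0 of 3 and 2 of 3 libraries. They were 15.0 ± 1.00 against 15.7 ± 0.58 of 18 NF-κB response genes, where Traf1 was called in 2 of 3 and 3 of 3. They were 14.7 ± 1.2 against 14 ± 0 of 16 innate sensing genes, where the RNA sensor gene Tlr7 was called in 2 of 3 and 0 of 3. Means were 10.7 ± 1.53 against 10.3 ± 1.2 of 16 immature and transitional B genes, where the transcription factor gene Lef1 was called in 2 of 3 and 0 of 3. They were 16.3 ± 1.2 against 16.7 ± 0.58 of 18 follicular and marginal zone genes, 13.3 ± 0.58 against 13.0 ± 1.00 of 15 germinal centre and plasma cell genes, 16.3 ± 0.58 against 15.7 ± 0.58 of 18 B cell receptor signalling and anergy genes, 19.3 ± 0.58 against 18.7 ± 0.58 of 20 cytokine receptor and STAT target genes, and 10.7 ± 0.58 against 11.3 ± 0.58 of 12 housekeeping genes (SD, n = 3 for all; exact permutation p between 0.6 and 1). Ms4a4c and Traf1 were called in 1 more DTx library, and Pou2f2, Nr4a3, Il10ra and Actb also differed by 1 library. Over the 247 distinct members of the 14 lists the mean was 219 ± 7.37 untreated and 219 ± 7.23 DTx (SD, n = 3; exact permutation p = 1). In the broad-mode libraries alone DTx had 9 members more and in the narrow-mode pair 16 fewer. By limma's camera 0 of 21 lists passed an adjusted p of 0.05 with a correlation of 0.01 or an estimated one. With the correlation of 0.01, 1 list had an unadjusted p under 0.05, stromal and endothelial genes, of which 5 were tested. Its unadjusted camera p was 0.0485 there and 0.114 with the estimated correlation.

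**Figure D1:**
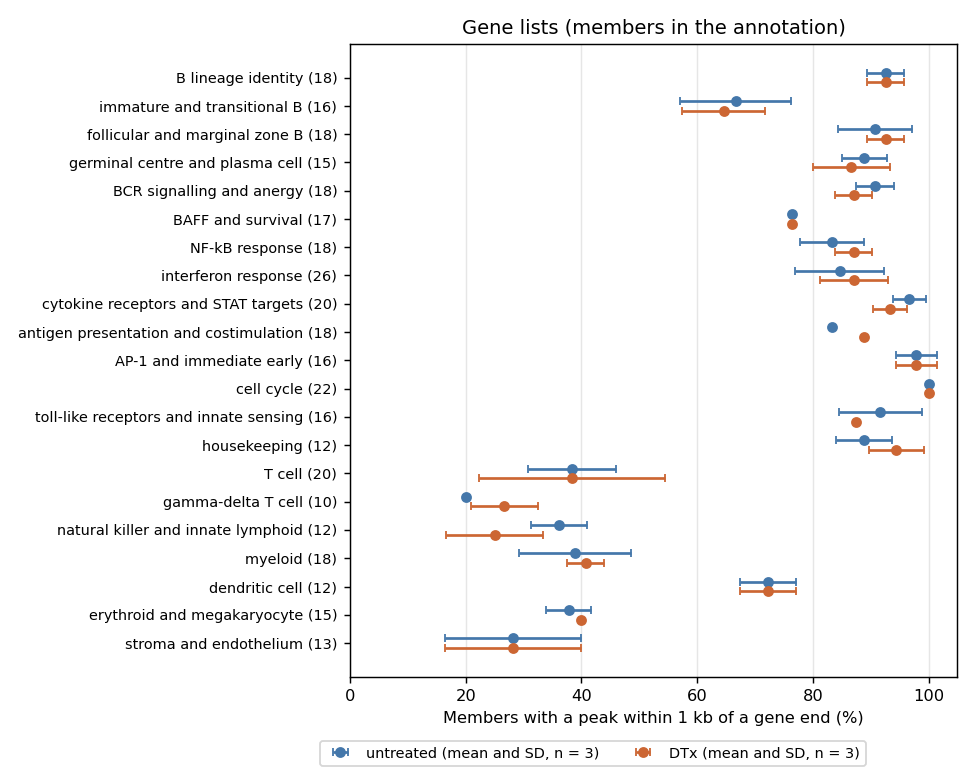
Share of each list's members (in percent, horizontal axis) with a peak within 1 kb of a gene end, as the mean and SD of 3 untreated and 3 DTx libraries, with the number of members in brackets. The 14 upper lists are of B cell and response genes and the 7 lower ones of markers of other cell types; antigen presentation stood at 15.0 against 16.0 of 18 members.

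Among all 21887 protein-coding genes, 10775 (49.2%) had a gene-end peak in all 6 libraries. Only 8 genes had one in 3 of 3 DTx and 0 of 3 untreated libraries, among them Gdap1, Gm38510, Ifne (interferon epsilon), Svop, Tmem176b, Cd80 and Afdn, and 1 gene, Gask1a, the reverse. Apart from Cd80 these were named after their values were seen. In the equal-length lists Ifne, Tmem176b and Cd80 stood at 3 of 3 against 0 of 3, and the others did not. Regrouping the libraries gave up to 225 such genes, and 9 of the 10 splits, the real one included, gave at least 9.

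Regions called in every DTx and no untreated library were far more numerous than the reverse in the deposited lists, with 495 DTx-only against 17 untreated-only regions. In the equal-length lists there were 181 against 282, the opposite direction. That direction was not stable, since without DTx replicate 1 there were 785 DTx-only against 672 untreated-only regions and in the broad-mode libraries 1850 against 1456. Under the strict criterion 61 DTx-only and 5 untreated-only regions remained, and 5 and 3 when only peaks with a −log10 q of at least 5 were used. Of the 61, 4 (6.56%) lay within 1 kb of a gene end, 29 in the body of a gene and 28 between genes, whereas 32.6% of the regions called in all 6 libraries lay within 1 kb of a gene end. Of regions called in any 3 of the 6 libraries 8.89% did, so a low share goes with regions called in few libraries. Within the broad-mode libraries (2 against 2) the strict counts were 1733 DTx-only and 17 untreated-only, and within the narrow-mode pair (1 against 1) they were 2931 and 7169, the opposite direction. Leaving out 1 library loosened the criterion and gave 510 DTx-only regions without untreated replicate 3, 391 without DTx replicate 1, 156 without untreated replicate 1, 121 without DTx replicate 3, 104 without DTx replicate 2 and 91 without untreated replicate 2. The largest values in the deposited lists were 2731 DTx-only regions without DTx replicate 1 and 156 untreated-only ones without untreated replicate 1. In equal-length lists they were 785 DTx-only regions without DTx replicate 1 and 740 untreated-only ones without untreated replicate 3.

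**Figure D2:**
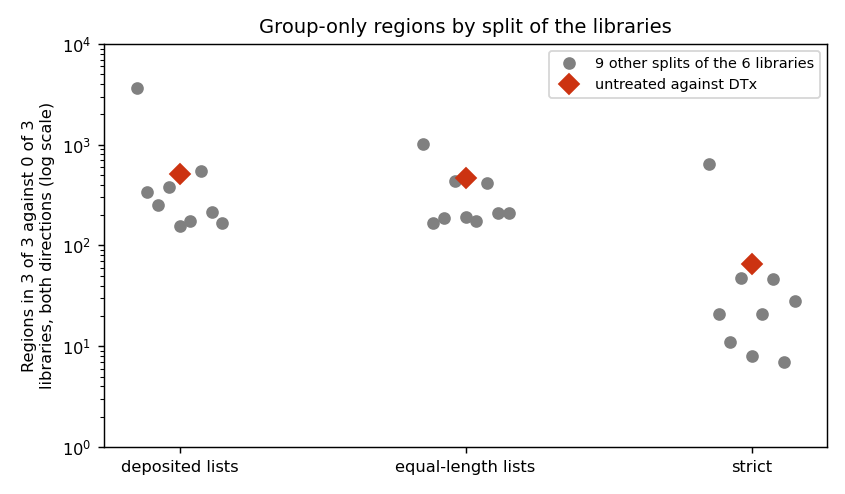
Regions called in 3 of 3 against 0 of 3 libraries, both directions together (vertical log axis), for the untreated against DTx grouping (red diamond) and for the 9 other splits of the 6 libraries (grey), under each of 3 criteria. The real grouping gave 512, 463 and 66 regions, and the highest other split 3686, 1005 and 641.

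The strict DTx-only region of highest rank lay on chromosome 7 from 30685162 to 30685531, 13.4 kb from 2200002J24Rik, at the 74.5th percentile or above in each DTx list. The next was inside Wdr70 (chromosome 15, 8097946 to 8098182), 1.03 kb from a gene end and at the 68.3rd percentile or above. Others lay 6.69 kb from Pip4p2 (chromosome 4, 14921953 to 14922255), inside Zfand4 (chromosome 6, 116282656 to 116282930), 22.7 kb from Raet1e (chromosome 10, 22212373 to 22212633) and inside Lca5 (chromosome 9, 83433775 to 83434091). A further region inside Awat2 (chromosome X, 100480450 to 100480781), one inside Usp47, a deubiquitinase gene (chromosome 7, 112085133 to 112085478), and one 15 bp from an end of the plexin gene Plxna2 (chromosome 1, 194816884 to 194817317) were at the 50.2nd percentile or above. The last of the 12 lay inside Plag1 (chromosome 4, 3924271 to 3924806), 25.7 kb from Ndfip2 (chromosome 14, 105232522 to 105232846) and inside Tfdp2, which encodes a partner of E2F factors (chromosome 9, 96217932 to 96218397).

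Raet1e is 1 of 3 genes on chromosome 10 that drew strict DTx-only regions within 200 kb, the others being H60b (22308217 to 22308488, 19.4 kb from the gene) and Raet1d (22345803 to 22346099, 15.8 kb from the gene). All 3 encode ligands of NKG2D, an activating receptor of natural killer and T cells. The window from 22212373 to 22412373 held 16 regions, of which 5 were called in all 6 libraries, 4 in every DTx and no untreated library, and 0 the reverse. The window was chosen after its regions were seen.

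**Figure D3:**
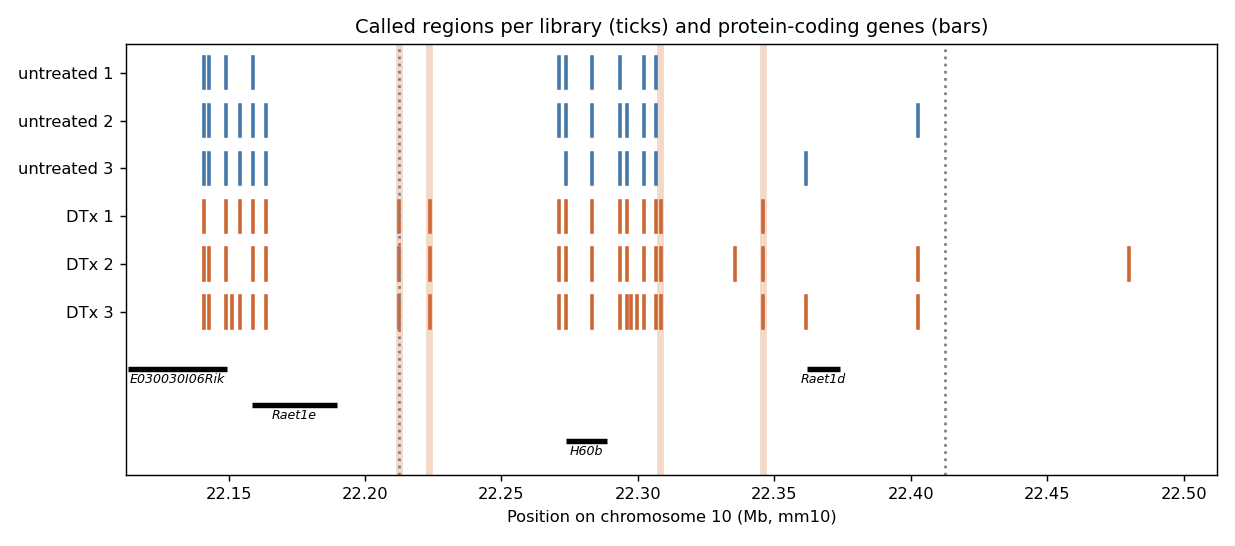
Called regions on chromosome 10 around Raet1e, H60b and Raet1d (horizontal axis, position in Mb on mm10), drawn as a tick at the midpoint of each region for each of the 6 libraries, with protein-coding genes as black bars. Shaded bands mark the 4 regions called in 3 of 3 DTx and 0 of 3 untreated libraries, and dotted lines the window from 22212373 to 22412373.

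The 5 strict untreated-only regions included 2 at Mid1, a ubiquitin ligase gene at the end of chromosome X. The first (169986670 to 169987527) lay inside the gene and was strong, at the 91.0th, 92.2nd and 87.2th percentile of untreated replicates 1, 2 and 3, with no DTx peak of any strength. The other (169993726 to 169994820) lay 2.93 kb beyond the gene, at the 20.2nd percentile or above. A region on chromosome Y (90799082 to 90799576), 54.0 kb from Gm52481, stood at the 76.9th percentile or above. The remaining pair lay 8.29 kb from Siah2 (chromosome 3, 58665729 to 58666664) and on chromosome 11 (117463312 to 117463706) with no gene end within 100 kb. The share of peaks on X was 2.45 ± 0.12% untreated and 2.5 ± 0.12% DTx, and Y held 7.0 ± 2.65 and 3.67 ± 2.08 peaks (SD, n = 3; exact permutation p = 1 and 0.3, Benjamini-Hochberg adjusted 1 and 0.5 over 10 measures). DTx minus untreated, the X share was -0.0278 points in the broad-mode libraries and 0.219 points in the narrow-mode pair, and Y held 1 and 8 fewer peaks.

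No list passed a test of excess near group-only regions, in a test with little power, since at most 0.0957 members of a list were expected near strict regions. In a test chosen after seeing the data, near equal-length DTx-only regions lay 2 antigen presentation genes, Cd80 and Nlrc5, where 0.235 were expected (Fisher's exact test, one-sided p = 0.0226, adjusted 0.582). Fisher's exact test gave 0 of 42 combinations of list and direction past an adjusted p of 0.05 for the strict regions, and 1 with an unadjusted p under 0.05, dendritic cell genes near DTx-only regions, through a single region inside Tcf4. The same count, also chosen after seeing the data, was 0 of 42 for the deposited and for the equal-length group-only regions, with 1 and 3 at an unadjusted p under 0.05. Igll1, a surrogate light chain gene of the immature and transitional list, lay 5.53 kb from a strict DTx-only region (chromosome 16, 16854823 to 16855146) and was named after this was seen.

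Around genes, limma set the number of peaks higher in DTx for 61 and lower for 28 of 12566 gene neighbourhoods at an adjusted p under 0.05, with 391 at an unadjusted p under 0.05. Among those of lowest p in each direction were Wdr70 (3 peaks in each untreated and 5 in each DTx library, log2 fold 0.65 ± 0.01 SE), 2310039H08Rik, Acot12 and Actn3 (3 and 4 each), and Dennd6b (7 and 5), Aldh5a1, Tomm20l and Yap1 (4 and 3 each) and Arpc1a (5 and 4), all at limma's adjusted p = 0.00198. Ptprc, which encodes CD45 and belongs to the B lineage list, had 10 and 9 peaks and Fosl1 of the AP-1 list 9 and 8. Adjusted over the list alone, limma also called 1 member each of the B cell receptor signalling and the myeloid list, and 0 members of the 17 lists other than these 4. Of the 89 genes, 88 had the same whole number of peaks in all 3 libraries of each group, so that the fit saw no spread, and Zadh2 (4, 4 and 4 against 6, 7 and 7) was the exception. Leaving out 1 library gave up to 189 higher (without untreated replicate 3) and 112 lower (without untreated replicate 1). With a floor on the variance, chosen after seeing the data, limma called 0 genes, with 400 at an unadjusted p under 0.05. That 0 says little of small differences, since the floored fit recovered 0.5% of genes changed 1.5-fold in simulation. An exact binomial test of the summed peaks called 0, with 1 unadjusted, and the fit called 0 on the deposited lists. None of the 89 is reported as a difference between the groups.

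In the deposited lists the median peak width was 526 ± 16.0 bp untreated and 475 ± 5.03 bp DTx (SD, n = 3; exact permutation p = 0.1, the smallest possible, Benjamini-Hochberg adjusted 0.5 over 10 measures), and no DTx library reached the lowest untreated one. The median was 40 bp lower in the broad-mode and 73 bp lower in the narrow-mode libraries. In equal-length lists, a comparison added after seeing the data, it was 594 ± 101 bp and 580 ± 52.2 bp (SD, n = 3; exact permutation p = 1), with differences of 70.5 bp in the broad and -183 bp in the narrow mode, so the lower width of the deposited DTx lists did not hold at equal length. The number of peaks averaged 45256 ± 10155 untreated and 53913 ± 8328 DTx (SD, n = 3; exact permutation p = 0.3), with 39632 against 58539 in the broad mode and 56503 against 44661 in the narrow mode, the opposite direction. Covered length was 28.2 ± 6.92 Mb and 30.7 ± 5.99 Mb (SD, n = 3; exact permutation p = 0.8), 9.74 Mb higher in the broad-mode DTx libraries and lower in the narrow-mode one, at 24.0 against 35.8 Mb. The share of peaks within 1 kb of a gene end was 25.7 ± 2.76% and 22.6 ± 2.38% (SD, n = 3; exact permutation p = 0.2), 27.2% against 21.2% in the broad mode and 22.7% against 25.3% in the narrow mode. In lists of equal length it was 28.7 ± 0.70% and 28.2 ± 0.03% (SD, n = 3; exact permutation p = 0.2).

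**Figure D4:**
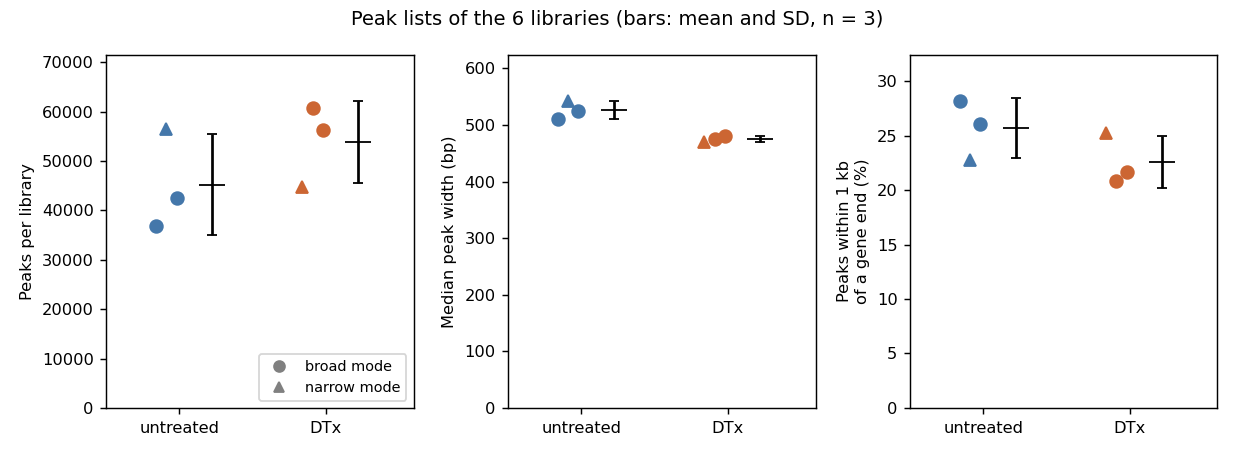
Number of peaks, median peak width (bp) and share of peaks within 1 kb of a gene end (%) for each of 3 untreated and 3 DTx libraries, with circles for broad-mode and triangles for narrow-mode lists and bars for the mean and SD. The DTx medians of width in these deposited lists lie between 470 and 480 bp and the untreated ones between 511 and 543 bp, whereas the groups overlap in the other panels.

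Over all 6 libraries, pairs within and between groups were alike to within 0.001 on average. The Jaccard index of the equal-length lists was 0.660 ± 0.050 over 6 pairs within groups and 0.661 ± 0.046 over 9 pairs between groups (SD). In the broad-mode libraries alone, with 1 pair per group, pairs within groups were 0.0427 higher than pairs between groups, and leaving out 1 library gave -0.0137 (without DTx replicate 2) to 0.0249 (without untreated replicate 3). The highest value was 0.740, between DTx replicates 2 and 3, and the lowest 0.588, between untreated replicates 1 and 3. A difference between within-group and between-group means as large was found in 9 of the 10 splits of the 6 libraries, the real one included. Regions called in at least 2 of 3 libraries numbered 43190 untreated and 52323 DTx, and 41853 were in both, which is 96.9% of the untreated and 80.0% of the DTx regions. In equal-length lists they numbered 35579 and 35920, with 32410 (82.9% of either) in both.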

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

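Settings limited to 1 calling mode, the variance floor, the binomial test, the 2 kb distance, width and covered length in equal-length lists and the list tests near deposited and equal-length group-only regions were chosen after seeing the data. Across 175 alternatives 90 kept the direction and side of the threshold or stayed within their limit, 74 moved and 11 were counted as turned in direction. The similarity difference, -0.000915 in the main setting, was counted as kept throughout. This includes settings where its sign turned, such as without untreated replicate 3 (0.0249). No value per library could pass 0.05 in the exact permutation test, so its p says nothing of stability. The median width of deposited lists differed by -58.7 to -42.7 bp with 1 replicate left out, but by -14 bp in equal-length lists. Tests of motifs, which need the genome sequence, and a promoter of 2 kb upstream and 500 bp downstream, which needs the strand, were not run. Overlap of at least 50% of the shorter peak was tried as 500 bp windows only. Depth is unknown, so a region not called cannot be told from one not sequenced deeply enough.

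A −log10 q of at least 5 gave 219 DTx-only and 5 untreated-only deposited regions, 73 and 130 in equal-length lists, and 5 and 3 strict ones. Fewer peaks remained by construction. Lower neighbourhoods rose from 28 to 57, and the cause of that rise was not tested. Ranking by fold enrichment gave 95 strict DTx-only regions, autosomes alone 2 strict untreated-only ones, since 3 lay on X and Y, and 500 bp windows 77.2% of reproducible regions shared, against 78.0%. Equal-length lists turned the difference over list members to -5 and in covered length to -0.795 Mb.

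The broad-mode libraries alone gave 8273 and 49 deposited, 1850 and 1456 equal-length and 1733 and 17 strict regions (DTx-only and untreated-only), and 643 higher and 243 lower neighbourhoods; 2 libraries against 2 loosen each criterion. The narrow-mode pair gave 2931 and 15704, 6169 and 7169, and 2931 and 7169, and turned the difference in peaks to -11842, in covered length to -11.8 Mb, in the gene-end share to 2.54 points and in list members to -16; the order of list lengths within the pair is the reverse of that of the group means.

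Neighbourhood calls (higher and lower) were 110 and 53 without a filter, 24 higher with 10 kb flanks, and 0 and 0 on deposited lists, with a floor on the variance and by the binomial test. The floor acts by construction on genes without spread within groups, and the cause was not tested for the others, among them the binomial test, whose 0 calls may come from low power.

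With each replicate left out in turn, the ranges were 638 to 2731 DTx-only and 22 to 156 untreated-only deposited regions, 332 to 785 and 397 to 740 in equal-length lists, 91 to 510 and 5 to 27 strict ones, and 92 to 189 higher and 51 to 112 lower neighbourhoods. Fewer libraries loosen each criterion, and without untreated replicate 1, the shortest list, the equal-length lists were also longer. Covered length ranged from -0.393 (without untreated replicate 1) to 6.36 Mb and list members from -2.17 to 4.83. Peaks per library ranged from 4409 to 14281 and the gene-end share from -4.59 to -1.85 points. The similarity difference ranged from -0.0137 to 0.0249, and was -0.0239 with 500 bp windows.

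Whether the replicate numbers pair the samples stays open. Deviations from the group means correlated at 0.204, -0.0217 and 0.147 for numbers 1, 2 and 3, and at -0.238 to 0.103 between different numbers. Not every sample correlated best with its own number, and 3 libraries per group are too few to decide. With the number as a block, limma called 60 higher and 29 lower neighbourhoods, the differences were 8657 peaks, 2.56 Mb, -51 bp, -3.12 points and 0.667 list members (exact sign-flip p = 0.25 at the lowest, the smallest possible), and the similarity difference was 0.0105; group-only counts have the same criterion with the block, 495 and 17, 181 and 282, and 61 and 5.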

Other observations

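The tests of placement, list length at the cluster, haplotype, sex and repeat copies for both clusters of regions and the antigen receptor counts were chosen only after the result was seen. Setting the group-only counts beside the other splits was planned, but the bound for reading those splits was chosen afterwards.

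Gene segments of the antigen receptors, which belong to none of the lists, were called in both groups. All 3 annotated V segments of the immunoglobulin lambda locus had a peak within 1 kb in each of the 6 deposited lists, and 3.0 ± 0 untreated and 1.67 ± 0.58 DTx in equal-length lists (SD, n = 3; exact permutation p = 0.1, the smallest possible). Of 162 kappa V segments, 57.7 ± 20.8 untreated and 72.7 ± 15.0 DTx had one, and of 183 heavy-chain V segments 9.67 ± 3.79 and 8.67 ± 2.08 (SD, n = 3; exact permutation p = 0.4 and 0.9). In equal-length lists the direction of the kappa segments turned, with 46.0 ± 9.85 untreated and 37.0 ± 2.0 DTx (SD, n = 3; exact permutation p = 0.4). At the T cell receptor loci the means were 1.67 ± 0.58 and 5.0 ± 3.0 of 136 alpha and delta V segments, 4.0 ± 1.0 in both groups of 35 beta segments, and 1.33 ± 0.58 and 2.00 ± 0 of 7 gamma segments (SD, n = 3; exact permutation p = 0.3, 1 and 0.4, Benjamini-Hochberg adjusted 0.8, 1 and 0.8 over 6 loci). In equal-length lists alpha and delta segments stood at 0.667 in both groups.

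Of 282 untreated-only regions 81 (28.7%) lay within 1 kb of a gene end, against 12 of 181 (6.63%) DTx-only regions, and their median widths were 929.5 and 396 bp. This difference was not tested. All but 5 of the 282 lay under a weaker DTx peak in the deposited lists, and their share near gene ends is that of all equal-length peaks (28.7% untreated and 28.2% DTx). The genes nearest to the untreated-only set included Myb and Sox4 of the immature and transitional list and Klf3 and S1pr3 of the follicular and marginal zone list (Fisher's exact test, adjusted p = 0.582 for each list). The Myb gene end was called in 3 of 3 untreated and 0 of 3 DTx equal-length lists, but in 3 of 3 and 2 of 3 deposited ones.

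The deposited lists held 495 DTx-only against 17 untreated-only regions, an excess of 478. Tables in which each library kept its number of regions and each region its number of libraries, with the calls otherwise swapped at random 100 times, gave an excess of 542 ± 21.5 (SD), with 95% of draws between 498 and 583. List length and each region's number of libraries, kept together, thus gave an excess at least as large. In the simulation, list length with independent noise only gave less, 257 DTx-only and 2 untreated-only regions. How much of the excess list length alone gives therefore depends on the model and is not settled. Among the 4 broad-mode libraries 99.4% of group-only regions were DTx-only (95% Clopper-Pearson interval 99.2 to 99.6%, counting error only). This argues against the mode as the only source, since the excess arose within 1 mode. The DTx lists were also the longer ones there, with 58539 against 39632 peaks on average. That share therefore cannot tell what the mode adds over all 6 libraries. In the narrow-mode pair, where the untreated list was the longer one, the share was 15.7%. An effect of the toxin treatment on the number of open regions, by depletion or otherwise, stays open and cannot be read from these lists.

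Of the 61 strict DTx-only regions, 3 lay within 200 kb at the NKG2D ligand genes Raet1e, H60b and Raet1d. Random draws of 61 regions from those called in 3 libraries reached 3 within 200 kb with a permutation p of 0.0042 over 10000 draws. The width was chosen with the cluster in view, so that p excludes nothing and chance placement stays open. List length stays open as well. The densest 200 kb of deposited DTx-only regions held 4, which 14 of 100 swapped tables also reached, but this looser set does not decide on the strict regions. A haplotype or copy-number difference between the mice cannot be told apart from open chromatin, since the 0 untreated-only regions in the window are what a copy carried by 1 group alone would also give. That γδ T cell depletion may open this locus in B cells is a hypothesis that these lists leave untested. The design could not tell it from an effect of the toxin.

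Of the 5 strict untreated-only regions, 3 lay within 2 Mb of the last called region of X or Y. Only 31 of 50601 regions called in at least 3 libraries lie there, with a hypergeometric p of 2.08e-09. That p excludes nothing, because the ends were singled out since these regions lay there, and 2 of the 3 are neighbours at Mid1, so chance placement stays open. Males in the untreated group alone are argued against by 0 untreated libraries with a peak within 1 kb of Kdm5d, Eif2s3y, Uty or Ddx3y, and no DTx library had one. A difference in repeat copy number near the pseudoautosomal boundary may give the same calls and cannot be told apart from a change of accessibility with these 3 regions; the mice's breeding is not given in the sources used here. The same end of X also held 2 deposited DTx-only regions, starting at 169303780 and 169798886.

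With 10 splits of 6 libraries into 3 and 3 no share under 0.05 can be had. The real grouping gave 512 group-only regions in the deposited lists, where 3 of the 10 splits, the real one included in this and the following counts, gave as many and the highest other gave 3686. It gave 463 in the equal-length lists, with 2 splits and 1005, and 66 under the strict criterion, with 2 splits and 641. Each time the highest split set untreated replicates 1 and 2 and DTx replicate 1, the 3 shortest lists, against the 3 longest, which points to a structure of the samples. It stayed highest in lists of equal length, so length alone was not shown to be that structure, and its cause was not tested. The neighbourhood fit called 89 genes in the real grouping, 2 of 10 splits gave as many, and that same split of short against long lists gave the highest other count, 178. Within the modes, deposited DTx-only and untreated-only regions numbered 8273 and 49 in the broad mode and 2931 and 15704 in the narrow mode.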
